A study of Mus musculus with 2 samples.

How the data were processed

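MicroRNA sequencing of RNA inserts under 30 nt was carried out on gastrocnemius of 2-month-old male B6CASTF1/J mice, with 1 library for each of 2 biological replicates, per the labels. The deposited values are raw counts of reads per microRNA gene, 1 table per library, on the mm10 assembly with the GENCODE M21 annotation, per the texts deposited with the tables. The aligner and the counter are not given in the sources used here. Each deposited table lists 2202 gene identifiers with 3 count columns, preceded by totals for unmapped, multi-mapping, no-feature and ambiguous reads. The tables carry no column names. From the values, the first count column was read as unstranded, the second as the strand of the microRNA and the third as the opposite strand, because the second held the larger total over genes. The second column was used throughout, and the other 2 serve as an alternative and as data outside the main measurement. All 2202 identifiers matched GENCODE M21, from which symbols, coordinates (1-based) and overlapping genes were taken. Of these, 1174 have a symbol that starts with Mir.

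Rows that name no gene stayed out of library sizes. Unmapped reads were 5.97% and 6.93% of all reads in replicates 1 and 2, reads with no feature 1.62% and 2.48%, and multi-mapping reads 75.2% and 74.4%. Reads matching several places are absent from the gene counts, so genes whose reads also match a copy elsewhere are underestimated to an unknown degree. Sharing was measured as 20 or more identical bases with a microRNA gene at another position. It was found for 1084 genes, which held 32.9% and 28.7% of the assigned counts. Copies outside annotated microRNA genes were not analysed here. Reads were counted on the C57BL/6J assembly, and the effect of CAST alleles on matching was not analysed here.

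Counts were divided by the library's total over microRNA genes and multiplied by 1000000 (CPM). A gene was called detected at 2 CPM in both libraries. Shares of single libraries carry exact Clopper-Pearson 95% intervals, and the limit for a count of 0 is 3 counts, 4.70 CPM in replicate 1 and 1.32 CPM in replicate 2. Replicate 2, with 3.56 times the counts, gives the narrower intervals. Intervals and limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules. They also leave out reads that match several places, so a count of 0 sets no limit for genes with such reads. With 2 libraries of 1 group there is no test between conditions. The binomial p-values set the difference between the libraries against counting error alone. The permutation and sign tests run over genes, pairs or clusters. Neither kind measures the spread between mice.

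Genes with 10 or more counts over both libraries (311) were compared by an exact two-sided conditional binomial test with Benjamini-Hochberg adjustment at 0.05. Ratios are replicate 2 over replicate 1 with a prior count of 0.5 added to each library for log2 values. Correlations used log2(CPM + 1). The coefficient of variation came from edgeR's common dispersion in an intercept-only model. Medians of lists with at least 3 tested members were placed among 10000 random lists drawn within 10 strata of mean CPM. Permutation tests used 100000 permutations. Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.

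The 18 gene lists, the tests of the report and the rule for named genes were fixed before the data were examined. The closing section names the tests chosen later. Named genes are the 25 of highest mean CPM and up to 4 members of each list with the highest mean CPM among those detected. Also named are the 5 highest and 5 lowest ratios among genes with a mean CPM of 100 or more that passed the binomial test. List members at 0 in both libraries could be named as well. Genes named outside the rule are said to be so.

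The binomial step was tested on simulated counts with the real means and totals of replicate 2 against replicate 1, over 311 genes, of which 200 were changed. It recovered 72% of genes raised 2-fold and 72% of those lowered 2-fold, 98% of those raised 4-fold and 84% of those lowered 4-fold. Of 111 unchanged genes it called 1. The simulated counts held counting error alone, with no further spread between libraries. These rates of recovery and false calls therefore do not hold for the real libraries, which differed by more. Simulated coefficients of variation of 10, 30 and 50% over 226 genes came back as 9.96, 29.8 and 47.9%. Of 100 random lists of 8 genes among 311, 4 fell outside the central 95% of matched lists. Alternatives tried were the unstranded column, TMM and DESeq2 scaling, other floors and pseudocounts, a negative binomial test, and each library left out.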

Results

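MicroRNAs, the short RNAs that guide silencing of messenger RNAs, were sequenced from gastrocnemius, the large muscle of the calf, of 2-month-old male mice. The mice were B6CASTF1/J, the first-generation cross of C57BL/6J and the wild-derived strain CAST/EiJ. The series holds 2 libraries of 1 group, labelled as biological replicates 1 and 2, and the labels name a separate mouse sample for each. With no second group, the data answer which microRNA genes were abundant among the reads assigned to a single gene, and how far the 2 libraries differed. Replicate 1 held 638779 counts assigned to microRNA genes and replicate 2 held 2272132, a ratio of 3.56. Of 3708776 and 14072300 reads, 17.2% and 16.1% were assigned to a single microRNA gene (16.7% ± 0.762, SD, n = 2). Reads that matched several places made up 75.2% and 74.4% and were not assigned to genes. All abundances below are therefore shares of the assigned reads, in counts per 1000000 microRNA counts of the library (CPM), and genes with a near-identical copy are read as uncertain.

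Most of the assigned microRNA counts came from few genes, and the leading ones were those of miR-378, miR-126 and miR-143. Mir378a, which lies in an intron of Ppargc1b, a coactivator of mitochondrial biogenesis, reached 163450 ± 33686 CPM (SD, n = 2), or 16.3% ± 3.37 of counts. It shares 20 bases or more with Mir378c, so its count is read as uncertain. Mir126a, within the endothelial gene Egfl7, followed at 105542 ± 34303 CPM, and Mir143, a microRNA of smooth muscle, at 99814 ± 28860 CPM. The SDs of Mir126a and Mir143 overlapped, and their order differed between the libraries: Mir126a had 81286 CPM in replicate 1 and 129798 in replicate 2, and Mir143 had 120222 and 79407. The top 3 genes held 36.9% ± 2.82 of counts, the top 10 held 67.4% ± 0.310 and the top 25 held 87.7% ± 0.121. Without Mir378a, the 10 leading genes of the remainder held 64.7%. Of the 2202 microRNA genes counted, 303 reached 2 CPM in both libraries, 138 reached 100 CPM, 55 reached 1000 CPM and 19 reached 10000 CPM. A further 1653 genes had no count in either library. Where the reads of a gene match 1 place, this allows up to 4.70 CPM in replicate 1 and 1.32 CPM in replicate 2. Where they match several places it sets no limit, since such reads are not counted.

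**Figure D1:**
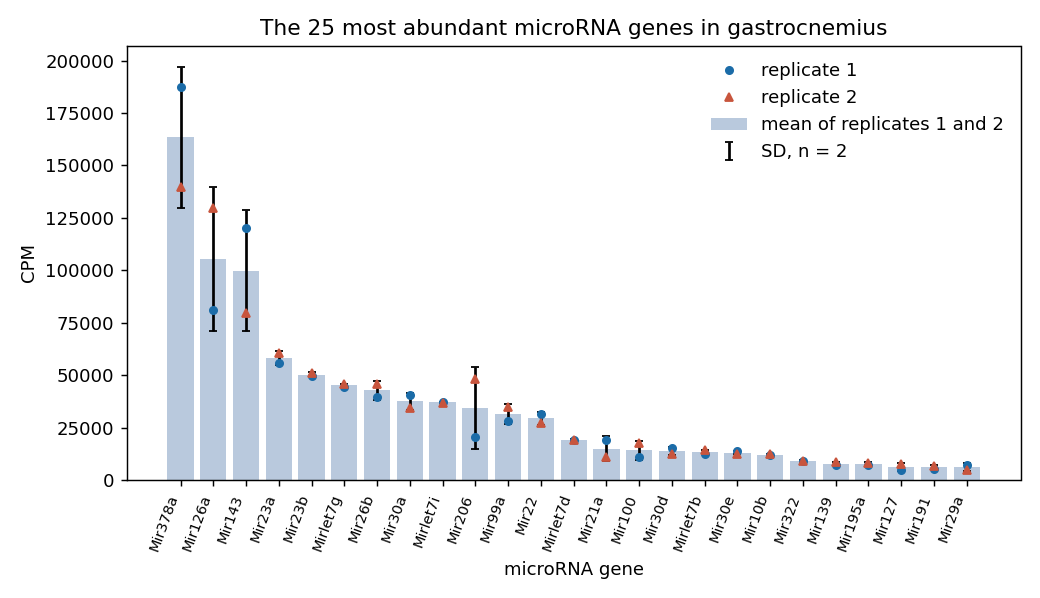
Abundance of the 25 most abundant microRNA genes in gastrocnemius, in CPM. Bars are means of replicates 1 and 2, error bars are SDs (n = 2) and symbols are the single libraries. Mir378a, at 163450 CPM, stands highest, and the symbols of Mir126a, Mir143 and Mir206 lie far apart.

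In the mm10 assembly with the GENCODE M21 annotation, Mir378a (ENSMUSG00000105200.1) lies on chromosome 18, 61397835 to 61397900, on the minus strand. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2, 26591357 to 26591429, in an exon of Egfl7 on the same strand. Mir143 (ENSMUSG00000065445.3) lies on chromosome 18, 61649196 to 61649258, outside any other annotated gene. The exact 95% Clopper-Pearson interval of the Mir378a share was 18.6 to 18.8% in replicate 1 and 13.9 to 14.0% in replicate 2, so the distance between the libraries was wider than their counting error. The same held for Mir126a, with 8.06 to 8.20% in replicate 1 and 12.9 to 13.0% in replicate 2. Mir378a and Mir126a each overlap another microRNA gene on the other strand. When the strand of the reads was ignored, Mir378a had 0 counts and Mir126a had 0 and 2, because such reads then counted as ambiguous.

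After the top 3 came the paired genes Mir23a, at 58132 ± 3389 CPM, and Mir23b, at 50261 ± 1245 CPM. Both share 20 bases or more with each other and are read as uncertain. Mirlet7g followed at 45057 ± 940 CPM, Mir26b at 42807 ± 4447, Mir30a at 37470 ± 4174 and Mirlet7i at 37067 ± 325. Mir206, the microRNA restricted to skeletal muscle, reached 34202 ± 19625 CPM, with 20325 CPM in replicate 1 and 48078 in replicate 2. The next were Mir99a (31319 ± 4676 CPM), Mir22 (29380 ± 3072 CPM), Mirlet7d (19046 ± 303 CPM) and Mir21a (14986 ± 5779 CPM), which lies in the untranslated region of Vmp1. Mir100 had 14212 ± 4553 CPM. Mir30d, Mirlet7b, Mir30e and Mir10b lay between 12003 and 13768 CPM. Mir322, Mir139, Mir195a, Mir127, Mir191 and Mir29a completed the 25, between 5969 and 9002 CPM. Of these 25, 24 were among the 25 most abundant of replicate 2 alone and 23 among those of replicate 1 alone.

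The 12 members of the striated muscle list, the myomiRs, summed to 37547 ± 20708 CPM (SD, n = 2), and 11 were detected. Mir206, on chromosome 1 at 20679010 to 20679082, gave most of that sum. The 3 microRNAs that lie in introns of myosin heavy chain genes formed a list of their own, which summed to 2004 ± 920 CPM. Mir499, in slow-type Myh7b, had 1301 ± 731 CPM and Mir208b, in the slow and cardiac gene Myh7, had 691 ± 180 CPM. Mir208a, in the cardiac gene Myh6, had 11.9 ± 8.02 CPM. Mir486, in an intron of Ank1, had 1011 ± 173 CPM. The genes of miR-1 and miR-133, among the best known microRNAs of muscle, were low, and they are named here after their values were seen. Mir1a-2 had 167 and 611 counts, Mir1a-1 had 9 and 25, Mir133a-1 had 10 and 28, Mir133a-2 had 6 and 11, and Mir133b had 14 and 27. These 5 genes summed to 316 CPM. Each shares 20 bases or more with another of the 5, and reads that match several genes are not in these counts, so the values are no measure of the abundance of miR-1 or miR-133.

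Families with several genes made up much of the rest. The let-7 family, which restrains proliferation, summed to 123467 ± 2088 CPM over 12 genes, all detected. Of these, 6 share 20 bases or more with another gene, so the sum leaves out their multi-mapping reads, as do the sums of the miR-30 (2 such genes), miR-29 (3) and miR-378 (2) families. The myomiR sum leaves out such reads for 7 of its 12 genes. The miR-30 family summed to 64968 ± 7045 CPM, with 6 of 7 genes detected and Mir30f at 0. The miR-29 family, which targets collagen transcripts, summed to 7364 ± 2745 CPM, of which Mir29a gave 5969 ± 1928 and Mir29c 1362 ± 811. The miR-378 family summed to 163621 CPM, nearly all from Mir378a, while Mir378d had 103 CPM, Mir378c and Mir378b were lower. The list of muscle development and regeneration summed to 12104 ± 549 CPM, led by Mir322 (9002 CPM) and Mir335 (2480 CPM, in an intron of the imprinted gene Mest), with Mir351 at 408 ± 256 and Mir483 at 151 CPM. The miR-17 to miR-92 cluster and its paralogs summed to 5319 ± 92.0 CPM, led by Mir93 (1523 CPM), Mir17 (1243 CPM), Mir20a (950 CPM) and Mir92-1 (642 CPM). The Dlk1-Dio3 imprinted cluster summed to 19480 ± 2550 CPM, with 44 of 51 members detected, led by Mir127 (6123 CPM), Mir411 (4952 CPM), Mir379 (1923 CPM) and Mir434 (881 CPM). Of 81 members of the Sfmbt2 cluster and its copies, 5 were detected and 72 had no count in either library. Their sum was 222 ± 39.2 CPM, led by Mir467e (98.1 CPM) and Mir467d (86.8 CPM), with Mir669o at 16.7 CPM. Mir467c had 2 counts in replicate 1 (3.13 CPM) and 40 in replicate 2 (17.6 CPM). These genes share sequence with other copies and are read as uncertain, as are Mir486, Mir378c, Mir92-1, Mir411, Mir199b, Mir199a-2, Mir129-1 and Mir219a-1.

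MicroRNAs of other cell types of muscle tissue were measured from fixed lists. The endothelial list held 105542 CPM, all but a trace from Mir126a. The vascular smooth muscle list held 102259 ± 29427 CPM, from Mir143 and from Mir145a (2445 ± 567 CPM). The fibroblast and mesenchymal list held 15747 ± 5589 CPM, of which Mir21a gave 14986, Mir214 714 and Mir199b 34.4 ± 15.6. Mir199a-2 had 6.26 CPM in replicate 1 and 19.4 in replicate 2. The erythroid list held 5432 ± 1052 CPM, from Mir451a (4788 CPM) and Mir144 (644 CPM). The leukocyte list held 2716 ± 245 CPM, with Mir155 at 1189, Mir150 at 1164, Mir142 at 213 and Mir223 at 150 CPM. Lists of tissues other than muscle had the following assigned counts. The epithelial list summed to 220 ± 7.53 CPM, led by Mir203 (172 CPM), with Mir200b and Mir205 at 12.1 and 9.86 CPM. Mir200c had 20.4 CPM in replicate 1 and 7.92 in replicate 2. The neural list summed to 33.2 ± 11.5 CPM, with 3 of 12 members detected, namely Mir137 (9.39 CPM in replicate 1 and 22.0 in replicate 2), Mir129-1 (7 and 25 counts) and Mir219a-1 (3.99 CPM). Of the 12, 10 share 20 bases or more with another gene, and their multi-mapping reads are not in these counts, so the sum is no measure of neural microRNAs. The list of liver and pancreatic islet summed to 27.2 ± 11.9 CPM, with Mir122 at 22.8 and Mir375 at 4.43 CPM.

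**Figure D2:**
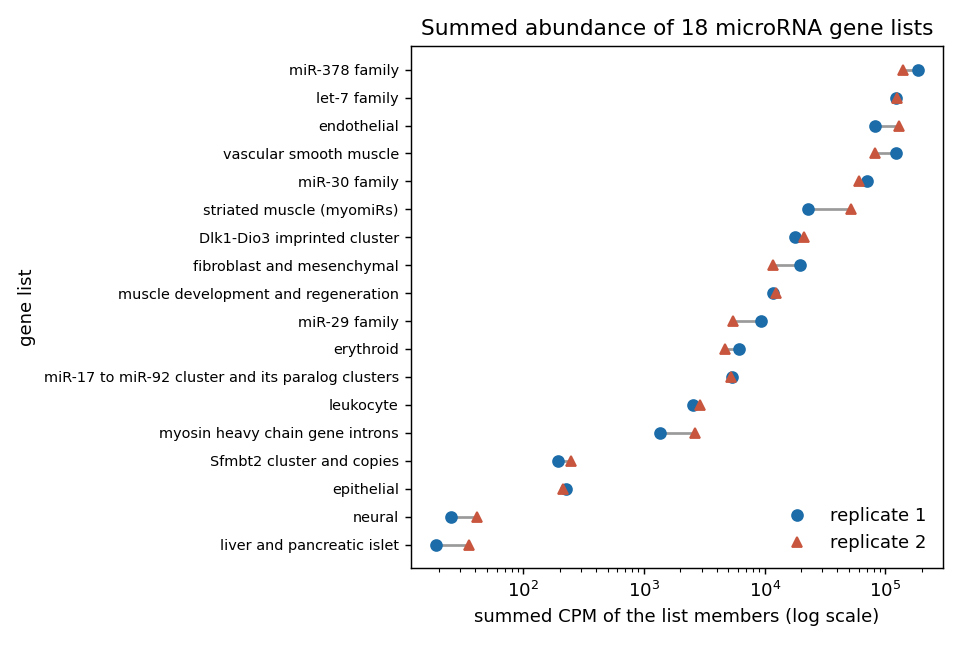
Summed abundance of the 18 fixed lists in CPM, on a logarithmic axis, with a circle for replicate 1 and a triangle for replicate 2 and a grey line between them. The lists run from 27.2 CPM (liver and pancreatic islet) to 163621 CPM (miR-378 family), and the myomiR and myosin intron lists lie to the right in replicate 2.

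Neighbouring microRNA genes, which often come from 1 transcript, were grouped when they lay on the same strand within 10 kb. There were 124 such clusters with 479 genes, 39 of them with at least 2 detected genes, and together they held 44.1% ± 0.445 of counts (SD, n = 2). In the clusters with the highest sums, 1 gene gave most of the assigned counts. Mir143 gave 97.6% of the 102259 ± 29427 CPM of its cluster with Mir145a, Mir23a gave 97.3% of the 59766 ± 3226 CPM of its cluster with Mir27a and Mir24-2, and Mir23b gave 91.4% of the 54982 ± 933 CPM of its cluster with Mir27b and Mir24-1. Mir99a gave 99.4% of its cluster with Mirlet7c-1. Mir27a, Mir24-2, Mir27b, Mir24-1 and Mirlet7c-1 are outside the rule for named genes and were named after their values were seen. These 5 share 20 bases or more with a gene elsewhere, so reads that match both are missing, and the shares of Mir23a, Mir23b and Mir99a in their clusters are read as uncertain. When strand was ignored the share of counts in clusters was 58.9%, since Mir378a and Mir126a then left the total.

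The abundances of the 2 libraries followed each other closely across genes and still differed by more than counting error. Over 367 genes at 2 CPM or more in at least 1 library, Spearman's rho was 0.953 (bootstrap 95% interval 0.934 to 0.967) and Pearson's r of log2(CPM + 1) was 0.968 (0.959 to 0.975). These are correlations across genes, which are not independent replicates. The biological coefficient of variation, the spread beyond counting error estimated by edgeR over 226 genes, was 24.7% (bootstrap 95% interval 21.4 to 28.0%). The bootstrap drew genes of the same 2 libraries, so the interval leaves out the uncertainty of having 2 mice. With 1 library per mouse, biological and technical spread cannot be told apart. DESeq2's median of gene-wise estimates, a measure unlike edgeR's common dispersion, was 13.5%, lower by over 1.5 times. The chi-square of the counts was 161 per degree of freedom over 311 genes, more than sampling noise. It cannot show that the libraries come from separate mice, which rests on the labels alone.

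Among the genes higher in replicate 2 were 4 of the 11 tested myomiRs. Mir206 was 2.37-fold higher there (95% interval of counting error 2.32 to 2.41), Mir499 was 2.32-fold higher (2.11 to 2.55), Mir208b 1.45-fold (1.30 to 1.63) and Mir486 1.27-fold (1.16 to 1.40). The largest ratios among genes with a mean CPM of 100 or more were those of Mir181a-2 (4.37-fold, 3.01 to 6.83), Mir423 (3.78-fold, 3.25 to 4.44), Mir351 (2.59-fold, 2.19 to 3.10) and Mir342 (2.39-fold, 1.99 to 2.91). Mir181a-2 shares 20 bases or more with Mir181a-1, which had 108 and 249 counts and a log2 ratio of -0.63, so its ratio is read as uncertain. Mir181a-1 is named after its values were seen. Among genes with a mean CPM of 100 or more that passed, Mir29c was the lowest in replicate 2 relative to replicate 1, at 0.408-fold (0.379 to 0.439). Mir1843b was at 0.488-fold, the annotated Snord43 at 0.518-fold, Mir1843a at 0.552-fold and Mir21a at 0.571-fold. Mir29c, Mir1843a and Mir1843b also share sequence with another gene. In all, 126 of 311 tested genes passed the exact binomial test with Benjamini-Hochberg adjustment, 72 of them higher in replicate 2 and 54 lower. With TMM scaling, which moved all log2 ratios by -0.06, 121 passed, 57 higher and 64 lower, so the balance of directions is not fixed by the data. Of the 126, 28 differed at least 2-fold, 21 higher and 7 lower. Among the 25 most abundant genes 23 passed, with a median absolute log2 ratio of 0.23. The binomial test compares these 2 libraries, not conditions. With the spread between them counted as noise, edgeR's exact test at the common dispersion called 4 genes, and 22 had an unadjusted p under 0.05. It sets 1 library against 1, with the noise estimated from the same difference, so it places genes against the average spread over genes and is no test of the mice. Those 4, taken from that test's result, were Mir543 (7 and 297 counts), Mir292 (13 and 0 counts), Mir181a-2 and Mir423. The origin of the Mir292 counts was not tested.

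**Figure D3:**
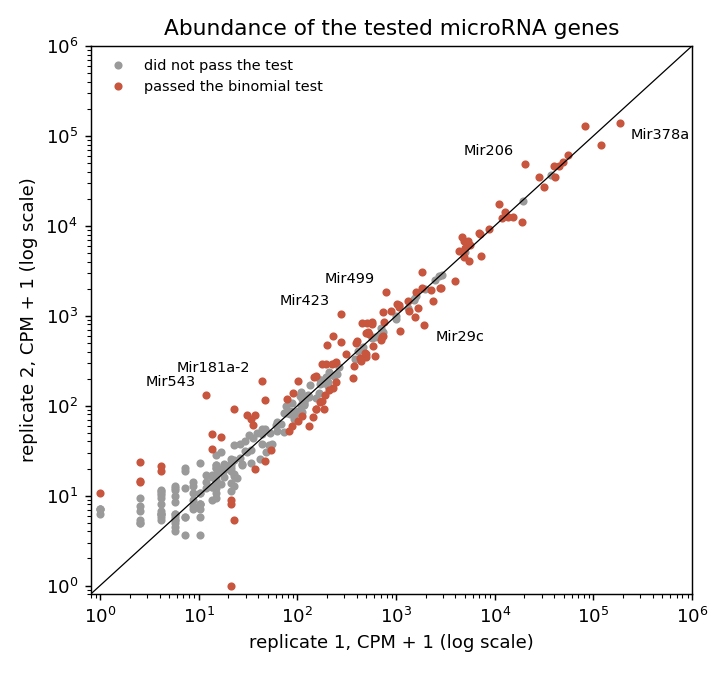
Abundance of the 311 tested microRNA genes in replicate 1 (horizontal) and replicate 2 (vertical), in CPM + 1 on logarithmic axes. The line marks equal values, and the 126 red points passed the exact binomial test between the libraries, with Mir206, Mir499, Mir423, Mir181a-2 and Mir543 above the line and Mir29c and Mir378a below it.

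Taken list by list, the myosin intron genes and the miR-29 family stood apart. The median log2 ratio of the 3 myosin intron genes was 1.21, at percentile 99.1 of 10000 random lists matched on mean CPM, whose central range was -0.70 to 0.89. That median is the ratio of Mir499 itself, with Mir208b below it (0.537) and Mir208a above it (1.34). All 3 also belong to the myomiR list, which did not stand apart (percentile 44.0). Mir499 and Mir208b were higher in replicate 2 by the test over all genes, and all 3 when p-values were adjusted over the list alone. Mir208a, with 4 and 40 counts, had an adjusted p of 0.0993 over all genes. The median of the 4 miR-29 genes was -0.85, at percentile 0.505, with a central range of -0.58 to 0.62. Mir29a (0.628-fold, 0.607 to 0.650) and Mir29c were lower in replicate 2, both also with p-values adjusted over the list alone. Mir29b-1, with 11 and 42 counts, and Mir29b-2, with 13 and 23, did not pass. Of the 4, all but Mir29a share 20 bases or more with another of the family, so the ratios of these 3 are read as uncertain. The same 2 lists stood apart with unstranded counts. They are 2 of 14 lists with enough members for a percentile. A percentile describes these libraries and is no test of the mice.

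The other 12 lists with a percentile lay within the central 95% of random lists, whatever the sum of their abundances. The myomiR sum was 2.28-fold higher in replicate 2, but Mir206 gave most of it, with 34202 of 37547 CPM. Of the 11 tested myomiRs 4 were higher, none lower and 7 did not pass (4 adjusted over the list alone). The median of the myomiRs stood at percentile 44.0. The let-7 sum was 1.02-fold, with 3 members higher and 9 not passing (3 adjusted over the list alone; percentile 54.9). With TMM scaling the let-7 sum was 0.982-fold, with 2 members higher and 2 lower, so the family had no fixed direction. The miR-30 sum was 0.858-fold, with 3 lower and 3 not passing (3 adjusted over the list alone; percentile 8.12). The miR-378 sum was 0.746-fold, with Mir378a alone lower (1 adjusted over the list alone; percentile 47.0). Of 44 tested members of the Dlk1-Dio3 cluster, 12 were higher, 5 lower and 27 did not pass (17 adjusted over the list alone; percentile 85.2). With TMM scaling 10 members of the Dlk1-Dio3 cluster were higher and 5 lower, and 4 miR-30 genes were lower in place of 3. Mir127 was 1.63-fold higher and Mir434 was at 0.615-fold, although both lie antisense to the coding sequence of Rtl1 in the same cluster. Of 11 tested members of the miR-17 to miR-92 list, 1 was higher, 3 lower and 7 did not pass (4 adjusted over the list alone, percentile 48.3). With TMM scaling 1 was higher and 4 lower. The muscle development list had 2 of 6 higher and none lower (2 adjusted over the list alone; percentile 77.3), of which Mir351 alone passed with TMM scaling, and the Sfmbt2 list 2 of 5 higher and none lower (2 adjusted over the list alone; percentile 92.1).

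MicroRNAs of the vessel wall, of blood and of connective tissue did not move together between the libraries. Mir126a, the endothelial microRNA, was 1.60-fold higher in replicate 2 (1.58 to 1.61). The smooth muscle pair Mir143 (0.661-fold, 0.655 to 0.666) and Mir145a (0.718-fold, 0.680 to 0.759) was lower, and so was the erythroid pair Mir451a (0.752-fold, 0.723 to 0.782) and Mir144 (0.812-fold, 0.730 to 0.906). These genes passed with p-values adjusted over the list alone as well, 1 endothelial, 2 smooth muscle and 2 erythroid. Among leukocyte genes, Mir155 (1.23-fold) and Mir150 (1.18-fold) were higher, Mir142 (0.731-fold) was lower and Mir223 did not pass (3 adjusted over the list alone; percentile 55.5). Among fibroblast genes, Mir214 (1.48-fold) was higher, Mir21a and Mir199b (0.510-fold) were lower and Mir199a-2 did not pass (4 adjusted over the list alone; percentile 26.6). Of 5 tested epithelial genes only Mir200c, with 13 and 18 counts, passed over all genes and was lower in replicate 2, and 0 passed adjusted over the list alone (percentile 38.7). None of the 3 neural genes (percentile 58.1) or of the 2 liver and islet genes passed, over all genes or adjusted over the list alone (0 in both).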

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

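The test of the strand partner reported here was chosen after the counts of the opposite-strand column had been seen, and Mir126b is named after its values were seen.

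The column of counts on the opposite strand, outside the main measurement, was not empty: it held 191685 counts in replicate 1 and 680772 in replicate 2, above the limit of 3 counts that a count of 0 allows. Of these counts, 99.99% fell in genes that overlap a microRNA gene annotated on the other strand, and 64 genes have such a partner. In replicate 1, all 28 such genes with opposite-strand counts held exactly the main-strand count of their partner, and in replicate 2, 33 of 34 did; the exception was Mir126b, with 294916 against 294918 counts of Mir126a. This is consistent with reads of Mir378a, Mir126a and other abundant genes being counted a second time in antisense annotations. The remaining 8 and 41 counts lay in genes with no partner, and no biological explanation was tested.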

How the results depend on the processing

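The scaling of the other named genes that passed and of the list sums was chosen after seeing the data. No paired analysis was possible because there is 1 group. Of the 10 genes with the highest and lowest ratios, 8 no longer passed in edgeR's exact test at the common dispersion. Of the genes called and named, Mir23b and Mirlet7g changed sign with TMM scaling (log2 ratios -0.0097 and -0.0177 in place of 0.0505 and 0.0425) and no longer passed. With TMM 4 others no longer passed, and the let-7 sum went from 1.02 to 0.982-fold. Mirlet7i, Mirlet7d, Mir30b and Mir20a, which did not pass with library totals, passed with TMM and were lower in replicate 2. Ignoring strand gave depths of 447110 and 1591442 counts, a top 10 share of 66.5%, a Spearman's rho of 0.931 and a cluster share of 58.9%, because reads on genes with an opposite-strand partner became ambiguous. It also moved 24 of the 25 leading genes by more than 1 SD. The top 10 share was 64.7% without Mir378a, and 67.2 to 68.7% with either library left out, where each library ranks its own genes. Spearman's rho was 0.904 with no filter on low counts and 0.967 at 100 CPM or more, and Pearson's r was 0.926 with a pseudocount of 0.1 CPM. DESeq2's median of gene-wise estimates gave a coefficient of variation of 13.5%. The common dispersion gave 23.5 to 27.9% over the 5 other alternatives in edgeR. These are unlike measures, a median of single-gene estimates and a value shared by all genes, so they need not match. The cause of the gap was not tested. The negative binomial test called 4 genes in place of 126, and 4 in place of 28 at 2-fold or more, because it counts the spread between the libraries as noise. The other counts of called genes lay between 114 and 126. Detection gave 242 to 378 genes over all alternatives, and the same 2 lists stood apart with unstranded counts. A scaling shifts every log2 ratio alike, so it cannot test the list percentiles. Depth limits the low genes: a count of 0 in replicate 1 allows up to 4.70 CPM where reads match 1 place.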

Other observations

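The Mir290 to Mir295 values, the within-cluster values, the split of clusters and the tests of shared sequence within lists were chosen after the results were seen. Mir302d, Mir99b, Mirlet7e, Mir125a, Mir181b-2, Mir18 and the miR-101 family were named after their values were seen. The cluster sign test and the tests of GC content, sequence relatives and cluster mates were set before their results. The comparison with 6 other lists, the pairs outside the Dlk1-Dio3 cluster, the demand that clusters outside the 4 lists pass and the 1 SD bound on pair correlations were added after results were seen; the bound first set for pairs was a correlation at or below 0.

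The Mir290 to Mir295 cluster on chromosome 7, known from embryonic stem cells, had 26 counts in replicate 1, over Mir291a (2), Mir292 (13), Mir293 (9) and Mir294 (2), or 40.7 CPM. The deeper replicate 2 had 0 counts, which allows up to 1.32 CPM. The labels do not give the sequencing runs, and carry-over of reads from another library was not tested, so these counts are not taken as expression in the muscle. Mir302d, another stem cell microRNA, had 4 counts in each library.

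Members of 1 cluster did not always share a ratio. Of Mir99b, Mirlet7e and Mir125a on chromosome 17, Mir99b was 1.67-fold higher in replicate 2 (95% interval 1.57 to 1.78), while Mirlet7e was at 0.980-fold (0.912 to 1.05) and Mir125a at 1.00-fold (0.943 to 1.07). Mir100 was higher as well, at 1.59-fold, as was Mir99a at 1.24-fold.

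In the myomiR, let-7, miR-30 and miR-29 lists, where the pattern was first seen, the 18 genes that share 20 or more bases with another had a median of 124 CPM and the 17 others 5969 CPM, a difference of -5.58 on the log2 scale. It is no rule for all such genes, since Mir378a, Mir23a and Mir23b share sequence too and were abundant. Genes without a copy were higher in 13 of 17 clusters (76.5%), which met the bound set beforehand against low transcription of these loci (exact sign test, p = 0.049), but that bound was wrong, because 8 of the 17 clusters hold members of the 4 lists (7 of 8 higher) and the rest gave 6 of 9 (exact p = 0.508). Reads that match several places are not in the counts, but how much of the difference this loss explains was not decided either. The pooled difference in 6 other lists was -5.71 (permutation within lists, p = 0.240). Of their 105 sharing genes, 79 belong to the Sfmbt2 list, where 72 of 81 members had no count. Low transcription and loss of such reads may each contribute and cannot be told apart with these few genes.

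The 2 libraries differed by more than counting error, and none of 3 candidate explanations was decided under the bounds finally used. The GC content of the hairpin correlated weakly with the log2 ratio over 146 genes (Spearman's rho 0.158, two-sided permutation p = 0.0576). If sequence set the library yield, related genes at separate loci would deviate together. The miR-29, miR-101, miR-99 and miR-100 families had been noticed before this test and were left out of it. The pair correlation of the other relatives was 0.0192 over 63 pairs (one-sided permutation p = 0.394). With the noticed families it was 0.109 over 66 pairs (one-sided permutation p = 0.148). If transcription differed between the mice, cluster mates of unlike sequence would deviate together, and theirs was -0.0501 over 116 pairs (permutation p = 0.681) and -0.231 over the 31 pairs outside the Dlk1-Dio3 cluster (permutation p = 0.910, SD of permuted pairs 0.177). By the bound first set, at or below 0, the value over 116 pairs counted against a difference in transcription. The value over 63 pairs did not meet that bound. Both lay within 1 SD of permuted pairs (0.0877 and 0.122), too close to 0 to decide. Many of the 63 pairs join let-7 genes, most of which differed little between the libraries, so that family weighs on their value. The value over 31 pairs, a part chosen later, lay over 1 SD below 0. These pairs include Mir181a-2 with Mir181b-2 (log2 ratios 2.13 and -0.497) and Mir92-1 with Mir18 (0.892 and -0.749). Mir181a-2 and Mir92-1 share sequence with another gene and are read as uncertain, so that value is uncertain too. Other pairs moved together, such as Mir143 with Mir145a (-0.598 and -0.478). The test therefore does not settle the matter. GC content, yield and a difference between the mice may each contribute and cannot be told apart here.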
